A study of Mus musculus with 5 samples.

How the data were processed

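The study measured RNA from sorted mouse spleen cells in 5 libraries: CD4 Treg (replicates 1 and 2), CD8 Treg (a single library) and CD49lo (replicates 1 and 2). Per the labels, lymphocytes were enriched for CD8 cells, stained and sorted, total RNA was extracted, and libraries were made by a standard Illumina protocol. The submitters' processing notes name CASAVA, STAR and the mm10 genome without versions. The processed table was deposited by the authors in RPKM (reads scaled to gene length and library depth), although it is presented as counts. Each value times its gene length, scaled, was a whole multiple of a smallest step in every library (100% of values within 0.02 of a whole number), so the reads behind each value could be recovered. All 5 sample columns of the table were used. The sample numbers skip 1, and the labels do not say whether a further library was made or of which population. Every CD8 Treg value rests on n = 1. Raw reads are not analysed here.

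The table held 35275 gene identifiers, of which 34490 occur in the reference annotation (GENCODE M21), 34465 on the same chromosome and strand and 24932 with the same start and end. Recovered depth was 6203090, 5441444, 6073243, 8354971 and 6564411 reads in genes, with 15123, 15710, 15818, 17472 and 15098 genes detected, in the order CD4 Treg replicates 1 and 2, CD8 Treg, CD49lo replicates 1 and 2. At the lowest depth, 1 read in a gene of 1 kilobase equals 0.184 RPKM.

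The analysis had been planned before the values were seen as a count model in edgeR, which was not used because the values were deposited as RPKM; DESeq2 was not used for the same reason, and recovered reads served for the filter, scaling, the prior and limma-voom. Instead a linear model was fitted with limma 3.58.1 in R 4.3.3 on log2(RPKM + 0.5), over all 5 libraries in 3 groups, with 2 residual degrees of freedom. RPKM were scaled by trimmed mean of M values (TMM) factors, computed from the recovered reads in code written for this work: 1.005, 1.011, 0.935, 1.015 and 1.038. Genes were tested if they had the equivalent of 10 reads at the median depth in at least as many libraries as the smallest group and 15 reads in total, which left 13298 genes, 13210 of them in the reference. Variances were moderated by empirical Bayes with a prior that follows the mean log2 RPM (reads scaled to library depth alone). The comparisons were CD4 Treg against CD49lo, CD8 Treg against CD49lo and CD8 Treg against CD4 Treg. P-values are two-sided and adjusted by Benjamini-Hochberg over all genes tested in a comparison, and a gene or list is named as called at an adjusted p under 0.05. The single CD8 Treg library is assumed to vary like the replicated groups.

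The fit was settled after results on these data had been seen. The first version kept genes with at least 1 RPKM in every library of a group and let the prior follow the mean log2 RPKM. The second took the read filter with that prior, and the third, reported here, lets the prior follow the mean log2 RPM. The choice rested on data simulated at a dispersion of 0.0116 with 200 changed genes in each of 3 runs, and not on the calls. Every gene and library was simulated at that dispersion, the single CD8 Treg library included. The rates that follow therefore compare the versions and are not error rates of the calls in these data. In the reported version unchanged genes made up 6.49%, 6.39% and 5.60% of the calls in the 3 comparisons, in the order given above. With the RPKM prior it was 11.0%, 11.3% and 11.1%, and with the RPKM prior and filter 9.14%, 9.80% and 14.7%. The reported version recovered 88.0%, 76.0% and 65.0% of 2-fold changes and 99.3%, 99.7% and 98.0% of 4-fold changes.

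The 28 gene lists, 403 of whose 408 genes occur in the table, were fixed before the values were seen. Some genes are in several lists, so the list results are not independent of each other. They were tested with camera from limma at a preset correlation between genes of 0.01, with Benjamini-Hochberg over the lists of a comparison. Tests with an estimated correlation and with fry were also run. With an estimated correlation, camera takes p from the 2 residual degrees of freedom and not, as with the preset, from the number of genes. A higher p under that setting therefore does not measure correlation between genes alone. For each list the members called over all genes tested are counted, and those called when adjusted over the list alone. Genes are named by a fixed rule: per comparison the 10 largest and 10 smallest log2 fold changes among called genes with at least 10 RPM in the higher group and no overlap between the groups' libraries, leaving out predicted genes, pseudogenes, small RNA genes and receptor segments. The check genes, up to 6 members per list with the smallest p and members said not to pass are also named; others are marked as chosen after the values were seen. Some genes that this rule names are not reported here. Where a group had 0 reads, the fold change is a bound against 3 reads over the group.

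Alternatives covered scaling (median-of-ratios, none), filter (none, stricter), limma-voom on recovered reads, robust moderation, the 2 groups alone, removal of receptor segments, a tested change above 1.5-fold, each replicated library left out and a replicate block. Chosen after seeing the data were pseudocounts of 0.1 and 1, removal of X and Y genes, removal of the 2 most abundant transcripts, and the first 2 versions of the fit. Shared calls were set beside the number that independent lists would share and beside 100 simulations of unchanged groups against shared CD49lo libraries. Near-identical copies of Rpl29 were found with blastn 2.17.0. Exact Clopper-Pearson intervals are 95% binomial intervals. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.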

Results

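RNA from sorted mouse spleen T cells was sequenced in 5 libraries. There were 2 libraries of CD4+ regulatory T cells (CD4 Treg), 1 of CD8+ regulatory T cells (CD8 Treg) and 2 of cells that the labels call CD49lo. The mice were C57BL/6 and 3 months old, and the labels name a CD8 enrichment and a flow cytometry sort before RNA extraction. The series sets out to compare CD4+ Tregs, CD8+ Tregs and CD8+ cells that resemble effectors. The CD49lo libraries are therefore the effector-like population only by elimination, since the labels do not spell the name out. The labels also do not say whether replicates came from separate animals, so the p-values measure the spread between these samples, which may be technical.

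The CD4 Treg libraries held 6203090 and 5441444 reads in genes, the CD8 Treg library 6073243, and the CD49lo libraries 8354971 and 6564411. A count of 0 allows up to 0.484, 0.551, 0.494, 0.359 and 0.457 RPM (reads scaled to library depth) in these libraries, in that order (3 reads per library). Across genes, the log2 values of replicates had a Pearson correlation of 0.972 in CD4 Treg and 0.963 in CD49lo. The CD8 Treg library correlated at 0.935 and 0.933 with the CD49lo libraries, and all other pairs of groups at 0.857 to 0.883. Genes are not independent replicates, so these values describe the libraries and carry no test. The CD8 Treg library stood apart in composition. The noncoding transcript Gm26917 took 6.86% of its reads (95% exact Clopper-Pearson interval 6.84 to 6.88), against 3.33% to 4.16% in the other 4 (half-widths of the exact intervals at most 0.0155). Ribosomal protein genes took 12.6% of its reads (exact interval 12.5 to 12.6), against 8.24% to 9.42% (half-widths at most 0.0242). Intervals and floors cover counting error only.

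The sort and lineage genes set CD4 Treg apart from the other libraries, while CD8 Treg and CD49lo both carried the CD8 lineage transcripts. Foxp3, the transcription factor of regulatory T cells (ENSMUSG00000039521, mm10 chromosome X, 7579676 to 7595243), reached 146 ± 0.405 RPKM in CD4 Treg (mean ± SD, n = 2). It stood at 0.387 RPKM in CD8 Treg (n = 1, as for every CD8 Treg value) and 1.23 ± 0.608 in CD49lo (n = 2). Cd4 (ENSMUSG00000023274, chromosome 6, 124864692 to 124888221) was at 210 ± 12.2 RPKM in CD4 Treg, 5.77 in CD8 Treg and 16.0 ± 0.633 in CD49lo. Cd8a (ENSMUSG00000053977, chromosome 6, 71373427 to 71379171) was at 0.382 ± 0.0423, 187 and 235 ± 28.0 RPKM in the same order. Zbtb7b, which directs the CD4 lineage, was at 44.9 ± 0.275, 3.23 and 7.02 ± 1.06 RPKM in that order. Cd4 and Zbtb7b passed the test as lower in CD8 Treg than in CD49lo (log2 fold changes -1.27 ± 0.15 and -0.88 ± 0.19, SE). Runx3, which directs the CD8 lineage, was at 24.9 ± 2.83, 60.6 and 62.6 ± 0.342 RPKM in the order above. Il2ra, which encodes CD25, was at 148 ± 7.93, 1.30 and 2.32 ± 0.892 RPKM. Il2rb, which encodes CD122, was at 272 ± 7.32, 302 and 146 ± 7.67 RPKM. Its log2 fold change over CD49lo was 0.92 ± 0.10 in CD4 Treg (SE; adjusted p = 0.000163) and 1.18 ± 0.12 in CD8 Treg (adjusted p = 0.00111). In CD8 Treg, Foxp3 (log2 fold change over CD49lo -0.85 ± 0.32, adjusted p = 0.185), Il2ra (-0.51 ± 0.27, adjusted p = 0.353), Cd8a (-0.19 ± 0.19, adjusted p = 0.657) and Crtam (0.16 ± 0.39, adjusted p = 0.87) did not pass the test.

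**Figure D1:**
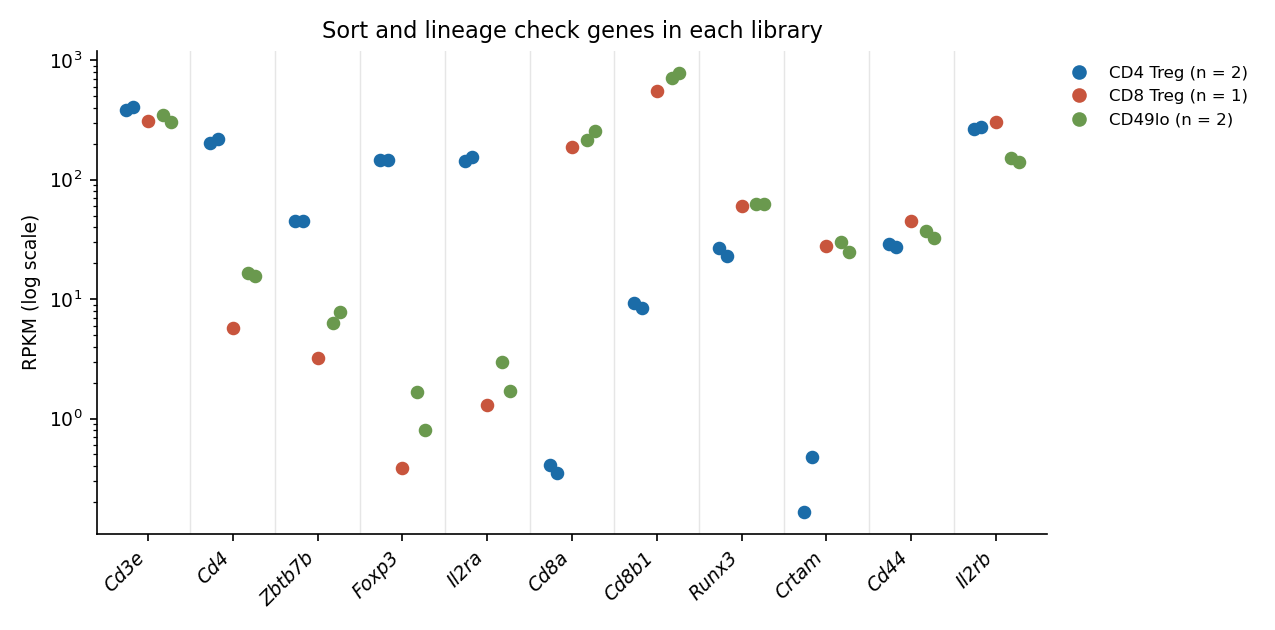
Expression of the 11 sort and lineage check genes in RPKM on a log axis, with 1 point per library, coloured by population. Foxp3 lies at 146 RPKM on average in CD4 Treg and at 0.387 RPKM in CD8 Treg, while Il2rb lies at 302 RPKM in CD8 Treg and at 146 RPKM on average in CD49lo.

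The first comparison asks how CD4 Treg differ from the CD49lo population. CD4 Treg carried the transcripts of classical regulatory T cells, and the CD49lo libraries those of cytotoxic lymphocytes and of dividing cells. The log2 fold change over CD49lo was 6.47 ± 0.26 for Foxp3 (± SE here and after every fold change; adjusted p = 7.76e-07). Fold changes rest on RPKM + 0.5, so those of genes near or below 0.5 RPKM in a group, such as Cd8a, Cx3cr1 and Klrc1 in CD4 Treg and Foxp3 in CD8 Treg, are set in part by the added value. The value was 6.18 ± 0.28 for Lrrc32 (adjusted p = 1.51e-06), which encodes the surface anchor of latent TGF-beta, and 5.77 ± 0.22 for Il2ra (adjusted p = 5.29e-07). On the other side it was -8.83 ± 0.61 for Gzma (adjusted p = 1.35e-05), a granule protease, and -7.15 ± 0.27 for Ccl5 (adjusted p = 5.29e-07), a chemokine. Klrd1, the CD94 chain of NK cell receptors, had 0 reads in CD4 Treg and was at least 404-fold lower there (floor of 3 reads over the group). Of 13298 genes tested, 2964 had an adjusted p under 0.05 and are named as called, 1257 higher and 1707 lower in CD4 Treg.

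Of the 29 genes of the CD4 Treg signature, 26 were higher in CD4 Treg over all genes tested and 27 adjusted over the list alone. Examples are the TNF receptor Tnfrsf4 (5.24 ± 0.18), Folr4 (4.23 ± 0.14) and the transcription factor Ikzf2 (3.92 ± 0.13), with adjusted p at most 2.85e-07. Some members that moved against their list are named here and below, chosen after the values had been seen. Klrg1, a receptor of terminally differentiated cells, was the 1 member that was lower (-2.40 ± 0.51, adjusted p = 0.00846). The list test called the signature (adjusted p = 2.94e-23), and the adjusted p was 0.205 with an estimated correlation. Of 17 costimulatory genes, 12 were higher and 2 lower (13 and 3 adjusted over the list alone; list adjusted p = 1.04e-07, and adjusted p = 0.215 with an estimated correlation), among them Tnfrsf18 at 2.60 ± 0.14. Of 19 TGF-beta pathway genes, 11 were higher and 0 lower (13 and 0 adjusted over the list alone; list adjusted p = 1.13e-06, and adjusted p = 0.273 with an estimated correlation), including Ski at 1.37 ± 0.11 and Itgb8 at 3.13 ± 0.34. Of 14 inhibitory receptor genes, 8 were higher and 2 lower (9 and 2 adjusted over the list alone; list adjusted p = 0.000797, and adjusted p = 0.228 with an estimated correlation). Ctla4 was higher by 3.55 ± 0.22, while Cd160 (-2.21 ± 0.27) and Havcr2 (-2.94 ± 0.42) were lower in CD4 Treg. The follicular list (6 higher and 1 lower of 10, the same adjusted over the list alone; list adjusted p = 0.00391, and adjusted p = 0.345 with an estimated correlation) included the transcription factor Maf at 3.16 ± 0.16. Interleukin receptors went both ways, 11 higher and 5 lower of 18 (12 and 5 adjusted over the list alone; list adjusted p = 0.00474 toward higher, and adjusted p = 0.238 with an estimated correlation). Il2ra and Il4ra (1.12 ± 0.10) were higher, and Il18rap (-4.14 ± 0.25) was lower. The highest adjusted p among the other genes named in this paragraph was 0.000919, for Havcr2.

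Immediate early and stress genes were also higher in CD4 Treg, 14 of 18 with 0 lower (15 and 0 adjusted over the list alone; list adjusted p = 3.97e-10, and adjusted p = 0.215 with an estimated correlation). Jun was higher by 3.06 ± 0.18 (adjusted p = 6.12e-06) and Fos by 3.02 ± 0.34 (adjusted p = 0.000216); such genes respond to activation and to cell handling. Of 23 interferon response genes, 10 were higher and 1 lower (13 and 1 adjusted over the list alone; list adjusted p = 1.13e-06, and adjusted p = 0.397 with an estimated correlation). Gbp3 was higher by 1.44 ± 0.11 (adjusted p = 2.59e-05), and Mx1 was the member that was lower (-1.24 ± 0.37, adjusted p = 0.0388).

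The CD49lo libraries held the higher levels of effector transcripts. Some of these genes are also in lists of other cell types, such as Gzma and Eomes (NK cells) and Itgax (dendritic cells). Transcripts of those cell types were also higher in CD49lo, as given below, so the cells that made these transcripts are not settled. All but 1 of 19 terminal effector genes were lower in CD4 Treg, with the same 18 adjusted over the list alone (list adjusted p = 1.71e-14, and adjusted p = 0.238 with an estimated correlation). The fractalkine receptor Cx3cr1 (-6.27 ± 0.37) and the transcriptional regulator Id2 (-3.24 ± 0.16) are examples; Prdm1 did not pass (0.45 ± 0.21, adjusted p = 0.172). Of 18 cytotoxic genes, 15 were lower and 1 higher, the same adjusted over the list alone (list adjusted p = 4.94e-10, and adjusted p = 0.289 with an estimated correlation). Nkg7, a granule protein, was lower by a log2 fold change of -5.58 ± 0.19, and perforin, Prf1, of -3.34 ± 0.21, while Srgn, a granule proteoglycan, was higher (0.54 ± 0.13, adjusted p = 0.0186). Of 15 CD8 memory genes, 10 were lower and 3 higher (11 and 3 adjusted over the list alone; list adjusted p = 0.000459, and adjusted p = 0.228 with an estimated correlation). The transcription factors Eomes (-5.16 ± 0.16) and Tbx21 (-4.75 ± 0.22) were lower, and Il2rb was among the 3 that were higher, with Cd27 and Bcl2. Of 20 NK cell receptor genes outside the Ly49 family, 17 were lower and 0 higher (19 and 0 adjusted over the list alone; list adjusted p = 9.39e-13, and adjusted p = 0.273 with an estimated correlation), including Klrc1 at -7.33 ± 0.41. Of 11 Ly49 receptor genes, 8 were lower and 0 higher (9 and 0 adjusted over the list alone; list adjusted p = 1.52e-05, and adjusted p = 0.215 with an estimated correlation), including Klra3 at -2.16 ± 0.44 (adjusted p = 0.00684). Of 24 cell cycle genes, 23 were lower and 0 higher (24 and 0 adjusted over the list alone; list adjusted p = 1.71e-14, and adjusted p = 0.273 with an estimated correlation), including Top2a at -3.54 ± 0.19 and Mki67 at -3.26 ± 0.21. The highest adjusted p among the other genes with a fold change in this paragraph was 1.00e-05, for Mki67.

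Transcripts of other cell types and of the sex chromosomes also separated these groups. Of 16 B cell genes, 15 were lower in CD4 Treg, the same adjusted over the list alone (list adjusted p = 2.33e-14, and adjusted p = 0.215 with an estimated correlation). Cd74 was at 50.5 ± 1.53 RPKM in CD4 Treg and 780 ± 23.7 in CD49lo (log2 fold change -3.91 ± 0.10, adjusted p = 6.33e-08). Of 14 monocyte, macrophage and neutrophil genes, 12 were lower and 1 higher, the same adjusted over the list alone (list adjusted p = 7.75e-08, and adjusted p = 0.238 with an estimated correlation). Lyz2 was lower (-6.17 ± 0.28, adjusted p = 1.51e-06), and Ctss was the member that was higher (0.47 ± 0.11, adjusted p = 0.0141). The dendritic cell list had 9 of 13 lower and 0 higher (10 and 0 adjusted over the list alone; list adjusted p = 5.73e-06, and adjusted p = 0.215 with an estimated correlation). The NK cell list had 10 of 12 lower and 1 higher (11 and 1 adjusted over the list alone; list adjusted p = 7.67e-07, and adjusted p = 0.273 with an estimated correlation); the 1 higher was Khdc1a, with 0 reads in the CD8 Treg and CD49lo libraries. The red cell and platelet list had 3 of 10 lower, Car2, Hba-a1 and Hba-a2 (4 adjusted over the list alone; list adjusted p = 0.00659, and adjusted p = 0.273 with an estimated correlation). Xist, transcribed from the inactive X chromosome of females, was at 35.5 and 27.2 RPKM in the CD4 Treg libraries, 0.0834 in CD8 Treg, and 0.0269 and 0 in CD49lo. The Y-linked Ddx3y was at 0.0701 and 0, 18.3, and 18.3 and 27.4 RPKM in the same order. The labels do not give the sex of the mice, and this split coincides with the CD4 Treg group.

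**Figure D2:**
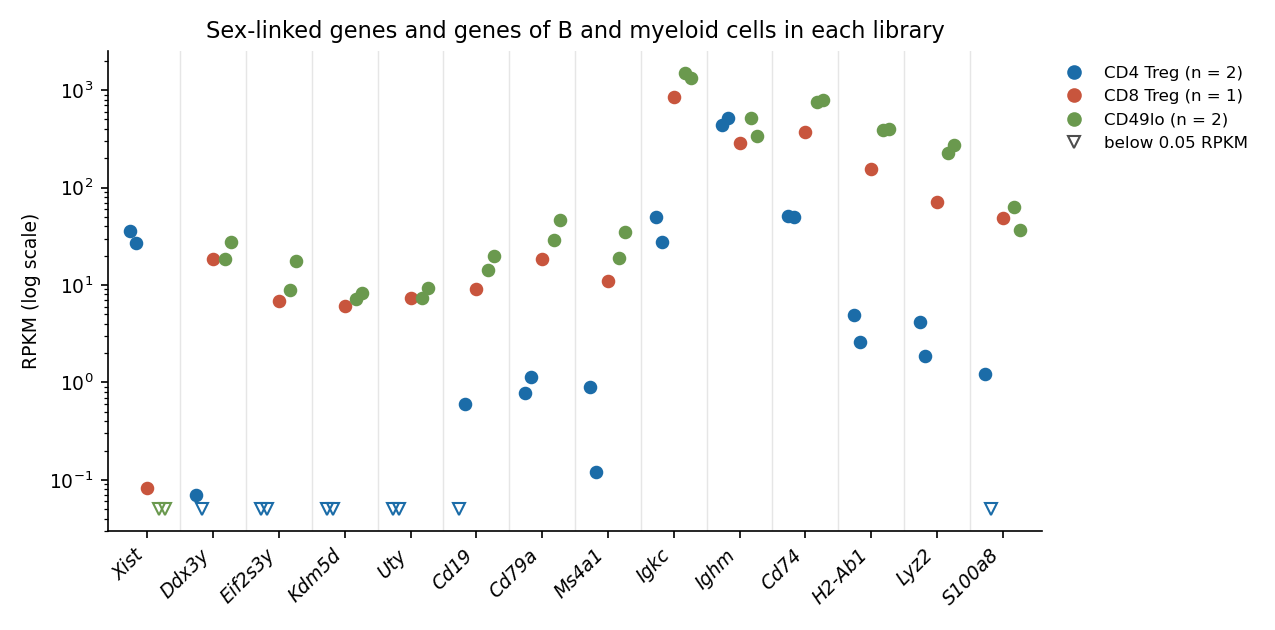
Expression of sex-linked genes and of genes of B and myeloid cells in RPKM on a log axis, with 1 point per library; open triangles mark values under 0.05 RPKM, placed at 0.05. The CD4 Treg libraries lie apart from the other 3 for each gene shown except Ighm, which was at 483 ± 55.0 RPKM in CD4 Treg, 285 in CD8 Treg and 427 ± 129 in CD49lo.

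The remaining lists of this comparison were not called. Of 15 naive and quiescence genes, 5 were higher and 3 lower (6 and 3 adjusted over the list alone; list adjusted p = 0.334), with Foxo1 higher (1.19 ± 0.13, adjusted p = 0.000201). Of 8 CD49 integrin genes and partner chains, 2 were higher and 3 lower (3 and 4 adjusted over the list alone; list adjusted p = 0.685). Itga4 was lower (-1.58 ± 0.11, adjusted p = 1.37e-05) and Itga6 higher (1.92 ± 0.13, adjusted p = 1.35e-05) in CD4 Treg. Of 17 chemokine receptor genes, 6 were higher and 8 lower (6 and 9 adjusted over the list alone; list adjusted p = 0.362), with Ccr4 higher (3.34 ± 0.30, adjusted p = 6.33e-05) and Ccr2 lower (-3.87 ± 0.18, adjusted p = 1.58e-06). T cell receptor complex genes (2 higher and 1 lower of 15, and 4 and 3 adjusted over the list alone; list adjusted p = 0.346), glycolysis genes (0 higher and 2 lower of 15, the same over the list alone; 0.959) and oxidative phosphorylation genes (0 of 22, the same over the list alone; 0.0535) were not called. The gamma-delta T cell list (2 higher and 2 lower of 9, and 3 and 3 adjusted over the list alone; 0.962) and the stroma list (1 higher of 4, the same over the list alone; 0.962) were not called either, nor were the 11 check genes as a list (5 higher and 4 lower, and 6 and 5 adjusted over the list alone; 0.513).

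The test called 19 of 28 lists, 8 higher and 11 lower, and 0 with an estimated correlation. The estimated correlation of the CD4 Treg signature was -0.0117, below the preset of 0.01, yet its unadjusted camera p rose to 0.00731. For that list the rise comes from the 2 residual degrees of freedom. The 0 calls therefore do not show that correlated genes made the list calls. By fry 18 were called. These left out the follicular, interferon response, and red cell and platelet lists and added the check genes and oxidative phosphorylation. Fits without 1 library keep 1 residual degree of freedom against 2 in the full fit, so fewer calls there also reflect that loss. Without either CD49lo replicate, most called genes that the naming rule covers lost their call. The gene count rested on each library: it was 1457 without CD4 Treg replicate 1, 1363 without CD4 Treg replicate 2, 451 without CD49lo replicate 1 and 528 without CD49lo replicate 2. The 20 genes with the most extreme fold changes kept their call in 20, 20, 16 and 16 cases in that order, and no sign turned.

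The second comparison asks how CD8 Treg differ from the CD49lo population. CD8 Treg carried more of several Ly49 receptor transcripts, a largely inhibitory family on NK cells and some CD8 T cells. It carried less of the transcripts of terminal effectors and dividing cells. The markers used in the sort are not stated here, so higher Ly49 and Il2rb transcripts could restate how the cells were sorted. Klra6 (ENSMUSG00000061769, chromosome 6, 130013033 to 130026954) was at 65.8 RPKM in CD8 Treg and 1.31 ± 0.117 in CD49lo (log2 fold change 5.32 ± 0.54, adjusted p = 0.00111). Gzmk (ENSMUSG00000042385, chromosome 13, 113171608 to 113225908), a granule protease, was at 1.52 RPKM and 145 ± 60.4 (-6.00 ± 0.48, adjusted p = 0.000397). Klrg1 was lower by a log2 fold change of -5.93 ± 0.63 (adjusted p = 0.00125), and Gzmb by -4.47 ± 0.45 (adjusted p = 0.00106). Of the genes tested, 705 were called, 228 higher and 477 lower in CD8 Treg. That is 32.3% higher, and the balance depends on the settings: it was 20.6% of 826 without a scaling factor, 50.8% of 689 by limma-voom, 85.2% of 580 without a filter and 54.9% of 295 with the first version of the fit.

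Of 11 Ly49 genes, 6 were higher and 0 lower in CD8 Treg (8 and 1 adjusted over the list alone; list adjusted p = 1.27e-06, and adjusted p = 0.349 with an estimated correlation). Besides Klra6 they included Klra7 (4.69 ± 0.68, adjusted p = 0.00516), Klra1 (4.34 ± 0.55, adjusted p = 0.00284), Klra10 (3.87 ± 0.56, adjusted p = 0.00508) and Klra3 (3.40 ± 0.54, adjusted p = 0.00785). Klra5 had 0 reads in CD49lo and was at least 18.9-fold higher. Klra9 (-0.95 ± 0.91, adjusted p = 0.638), Klra2 (-1.45 ± 0.56, adjusted p = 0.196) and Klra17 (-1.21 ± 0.66, adjusted p = 0.368) had values below 0 and were not called. Genes of this family are similar in sequence, which was not measured here, so the assignment of reads among them is uncertain. Of 15 naive and quiescence genes, 4 were higher, including Satb1 (1.37 ± 0.17), Il7r (1.11 ± 0.14) and Lef1 (0.68 ± 0.13), and Ccr9 was lower (-2.02 ± 0.36). The count was 8 higher and 2 lower adjusted over the list alone (list adjusted p = 0.000699, and adjusted p = 0.414 with an estimated correlation). Of 18 interleukin receptor genes, 5 were higher and 1 lower (8 and 2 adjusted over the list alone; list adjusted p = 0.00221, and adjusted p = 0.349 with an estimated correlation). Those higher included Il2rb and Il4ra (1.19 ± 0.12), and the 1 lower was Il10ra (-0.93 ± 0.18). Of 15 CD8 memory genes, 4 were higher and 3 lower (9 and 4 adjusted over the list alone; list adjusted p = 0.011 toward higher, and adjusted p = 0.36 with an estimated correlation). The survival factor Bcl2 was higher (1.69 ± 0.13), and Ly6a was lower (-1.97 ± 0.27). Il2rb and Il7r are in both the CD8 memory and the interleukin receptor list, and Il7r is also in the naive list. The calls of these lists thus rest in part on the same genes. The highest adjusted p among the called genes of this paragraph without their own was 0.0174, for Il10ra.

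Of 19 terminal effector genes, 12 were lower and 0 higher (16 and 0 adjusted over the list alone; list adjusted p = 7.22e-13, and adjusted p = 0.36 with an estimated correlation). Examples are S100a4 (-2.99 ± 0.24), Id2 (-2.21 ± 0.19) and the galectin Lgals1 (-1.87 ± 0.16); Tbx21 did not pass (-0.00 ± 0.27, adjusted p = 1). Of 18 cytotoxic genes, 4 were lower, the granzymes Gzmk, Gzmb and Gzma (-3.47 ± 0.74, adjusted p = 0.0295, called in 10 of 19 alternatives with values of -4.64 to -2.30) and the protease inhibitor Serpinb6b (-1.01 ± 0.18, adjusted p = 0.0147), and 0 higher. Prf1 (-0.21 ± 0.26, adjusted p = 0.72) and Nkg7 (-0.42 ± 0.23, adjusted p = 0.375) did not pass. The count was 7 lower and 2 higher adjusted over the list alone (list adjusted p = 0.0122, and adjusted p = 0.732 with an estimated correlation). Of 14 inhibitory receptor genes, 7 were lower and 0 higher (9 and 1 adjusted over the list alone; list adjusted p = 1.96e-05, and adjusted p = 0.349 with an estimated correlation), including Lag3 (-2.56 ± 0.24), Ctla4 (-2.62 ± 0.27) and Pdcd1 (-2.47 ± 0.33). Of the 29 genes of the CD4 Treg signature, 9 were lower and Il2rb alone was higher (13 and 3 adjusted over the list alone; list adjusted p = 0.00718, and adjusted p = 0.349 with an estimated correlation). Nrp1 was among the lower (-2.08 ± 0.18), and Ikzf2, which encodes Helios, did not pass (0.55 ± 0.16, adjusted p = 0.0885). Of 8 CD49 integrin genes and partner chains, 4 were lower, Itga4 (-2.73 ± 0.13), Itgb1 (-0.80 ± 0.14), Itgb7 (-0.66 ± 0.12) and Itga1 (-2.47 ± 0.57), and 0 higher (4 and 1 adjusted over the list alone; list adjusted p = 0.0459, and adjusted p = 0.414 with an estimated correlation). Of 10 follicular genes, Pdcd1, Maf (-1.30 ± 0.19) and Cd200 (-2.13 ± 0.39) were lower and Cxcr5 higher (0.69 ± 0.16), with 6 lower and 1 higher adjusted over the list alone (list adjusted p = 0.0103, and adjusted p = 0.539 with an estimated correlation). Of 24 cell cycle genes, 15 were lower and 0 higher (22 and 0 adjusted over the list alone; list adjusted p = 1.53e-14, and adjusted p = 0.414 with an estimated correlation), with Ccnb2 at -3.25 ± 0.44 and Top2a at -2.07 ± 0.23. The highest adjusted p among the called genes of this paragraph without their own was 0.0406, for Itga1.

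**Figure D3:**
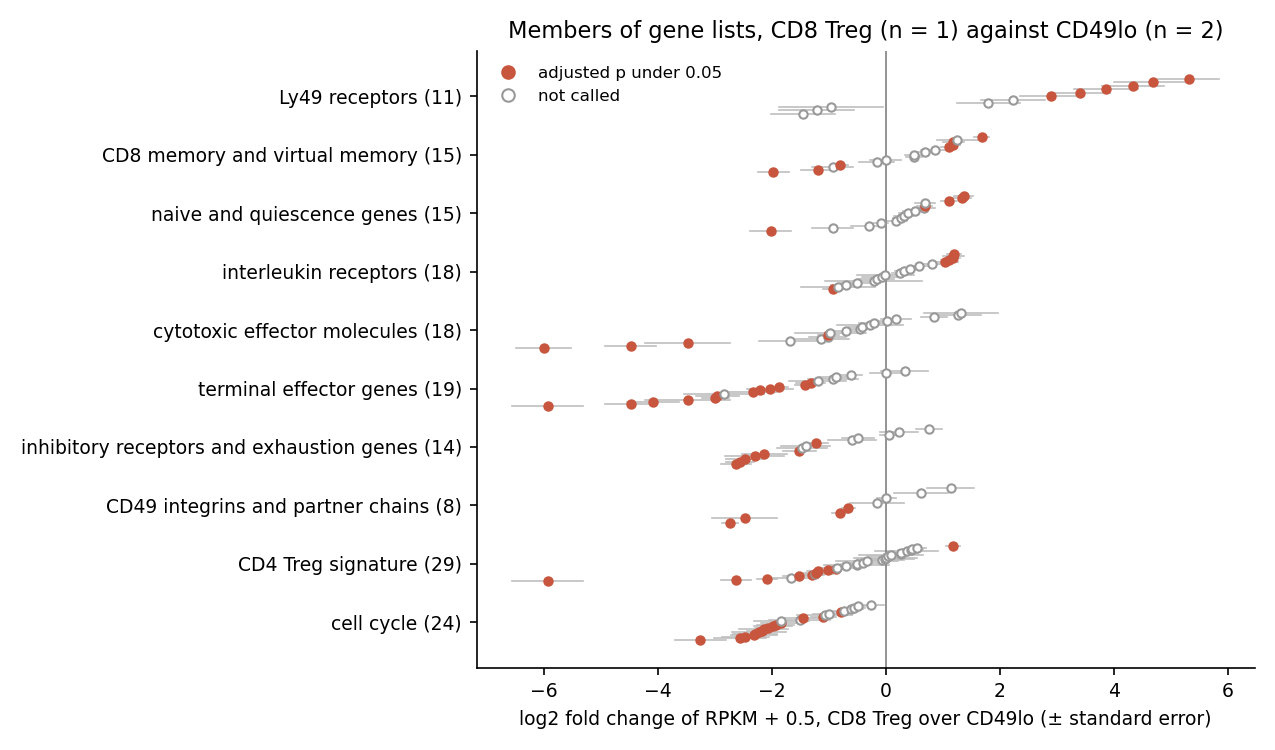
Log2 fold changes of CD8 Treg over CD49lo (± standard error) for the members of 10 gene lists, with the number of members in parentheses; filled points have an adjusted p under 0.05. The called Ly49 genes lie on the right, up to 5.32 for Klra6, and the called terminal effector genes on the left, down to -5.93 for Klrg1; values of genes near or below 0.5 RPKM in a group depend on the pseudocount.

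Other cell types' genes moved with this comparison too. The dendritic cell list shares Itgax with the terminal effector list and Ccr9 with the naive list. The NK cell list shares Gzma with the terminal effector and cytotoxic lists. Whether those differences came from T cells or from other cells was not tested. Of 16 B cell genes, 3 were lower in CD8 Treg, Cd74 (-0.94 ± 0.12, adjusted p = 0.00289), H2-Eb1 (-1.41 ± 0.30, adjusted p = 0.0293) and H2-Ab1 (-1.19 ± 0.29, adjusted p = 0.0491), and 0 higher (8 and 0 adjusted over the list alone; list adjusted p = 9.31e-07, and adjusted p = 0.349 with an estimated correlation). Of 13 dendritic cell genes, 5 were lower and 0 higher (10 and 0 adjusted over the list alone; list adjusted p = 7.57e-07, and adjusted p = 0.349 with an estimated correlation), with Tcf4 at -1.82 ± 0.33 (adjusted p = 0.0138). The monocyte, macrophage and neutrophil list (0 higher and 2 lower of 14, and 4 lower adjusted over the list alone; list adjusted p = 0.0726) and the NK cell list (0 higher and 1 lower of 12, Gzma, and 4 and 1 adjusted over the list alone; 0.235) were not called. The lists of gamma-delta T cells (1 higher, Cd163l1, and 1 lower, Maf, of 9, the same over the list alone; 0.606), red cells and platelets (Car2 lower of 10, and 2 adjusted over the list alone; 0.373) and stroma (0 of 4, the same over the list alone; 0.226) were not called.

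Among the other lists, NK cell receptor genes outside the Ly49 family had 0 higher and 2 lower of 20 (1 and 6 adjusted over the list alone; list adjusted p = 0.11), Klrg1 and Cd226 (-1.26 ± 0.21, adjusted p = 0.00914). Costimulatory genes had 1 higher, Tnfsf8, and 4 lower of 17 (4 and 5 adjusted over the list alone; 0.572), and chemokine receptor genes 1 higher, Cxcr5, and 4 lower of 17 (4 and 6 adjusted over the list alone; 0.519). TGF-beta pathway genes had 1 higher, Smad7, and 1 lower, Itgav, of 19 (2 and 3 adjusted over the list alone; 0.572). Immediate early genes had 1 higher, Cd69, and 1 lower, Nr4a1, of 18 (1 and 2 adjusted over the list alone; 0.868). Interferon response genes had 2 lower of 23, including Gbp3 (3 adjusted over the list alone; 0.135). T cell receptor complex genes had 1 lower of 15, Lat (the same over the list alone; 0.572), glycolysis genes 1 lower of 15, Slc2a3 (the same over the list alone; 0.931), and oxidative phosphorylation genes 0 of 22 (the same over the list alone; 0.226). The check genes had 1 higher and 2 lower of 11 (2 and 2 adjusted over the list alone; 0.572).

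The test called 13 of 28 lists, 4 higher and 9 lower, and 0 with an estimated correlation, a setting that again rests on 2 residual degrees of freedom. By fry 4 were called, the Ly49, CD8 memory, inhibitory receptor and dendritic cell lists. The terminal effector and cell cycle lists were among those that fry did not call. Fits without a CD49lo replicate set 1 library against 1, keep 1 residual degree of freedom and take their spread from the CD4 Treg libraries alone. CD8 Treg is a single library that the fit assumes to vary like the others, so this comparison has no replicate check on its side and its calls rested on the spread of all 4 replicated libraries: 14 genes were called without CD49lo replicate 1, 92 without CD49lo replicate 2, 199 without CD4 Treg replicate 1 and 123 without CD4 Treg replicate 2. Of the 20 genes with the most extreme fold changes, 0 stayed called without CD49lo replicate 1 and 4 without CD49lo replicate 2 (Klra6, Klra7, Klra10 and Cd163l1), with no sign turned; 15 stayed called without CD4 Treg replicate 1 and 12 without CD4 Treg replicate 2. The integrin list lost its call without any 1 of the 4 replicated libraries, the CD8 memory and follicular lists without CD49lo replicate 1, and the cytotoxic list without CD49lo replicate 2.

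The third comparison asks how the CD8 Treg and CD4 Treg populations differ. CD8 Treg held little of the transcripts that mark CD4 Treg and more of those of NK-like and memory CD8 cells. Foxp3 was lower in CD8 Treg by a log2 fold change of -7.31 ± 0.32 (adjusted p = 2.09e-06), Il2ra by -6.28 ± 0.27 (adjusted p = 2.06e-06) and Ctla4 by -6.17 ± 0.27 (adjusted p = 2.06e-06). Cd8a was higher by 7.84 ± 0.19 (adjusted p = 5.73e-08) and Ccl5 by 6.14 ± 0.33 (adjusted p = 6.64e-06). Klrd1, Klra7 and Klra6 had 0 reads in CD4 Treg and were at least 449-fold, 331-fold and 307-fold higher in CD8 Treg (floor of 3 reads over the group). Penk, which encodes proenkephalin, had 0 reads in CD8 Treg and was at least 104-fold lower there. Of the genes tested, 2241 were called, 1131 higher and 1110 lower in CD8 Treg. The split was 945 and 1367 without a scaling factor, 882 and 395 without a filter, and 226 and 113 without CD49lo replicate 2. The Xist and Ddx3y split between the CD4 Treg and the other libraries applies here as well (Xist adjusted p = 2.82e-05).

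Of the 29 genes of the CD4 Treg signature, 28 were lower in CD8 Treg, the same adjusted over the list alone (list adjusted p = 1.22e-26, and adjusted p = 0.15 with an estimated correlation). Il2rb was the 1 member that did not pass (0.26 ± 0.12, adjusted p = 0.182). Folr4 (-5.11 ± 0.17) and Nrp1 (-5.08 ± 0.18) are examples. Of 17 costimulatory genes, 12 were lower and Tnfsf14 (2.08 ± 0.30) and Tnfsf8 (1.15 ± 0.23) were higher (14 and 2 adjusted over the list alone; list adjusted p = 1.36e-07, and adjusted p = 0.15 with an estimated correlation). Of 14 inhibitory receptor genes, 10 were lower and Cd160 was higher (2.45 ± 0.33), the same adjusted over the list alone (list adjusted p = 9.52e-07, and adjusted p = 0.15 with an estimated correlation). Pdcd1 was lower by -3.85 ± 0.33 and Tigit by -3.76 ± 0.29. Of 10 follicular genes, 7 were lower, with Maf at -4.46 ± 0.19, and Pou2af1 was higher at 2.67 ± 0.33 (8 and 1 adjusted over the list alone; list adjusted p = 5.24e-05, and adjusted p = 0.372 with an estimated correlation). Of 19 TGF-beta pathway genes, 11 were lower and 0 higher (12 and 1 adjusted over the list alone; list adjusted p = 3.16e-06, and adjusted p = 0.372 with an estimated correlation), including Itgae (-3.39 ± 0.31). Of 18 immediate early genes, 13 were lower and 0 higher (14 and 0 adjusted over the list alone; list adjusted p = 4.56e-09, and adjusted p = 0.15 with an estimated correlation), including Dusp1 (-3.54 ± 0.22) and Jun (-2.81 ± 0.22). Of 23 interferon response genes, 10 were lower and 0 higher (14 and 0 adjusted over the list alone; list adjusted p = 1.08e-07, and adjusted p = 0.464 with an estimated correlation), including Gbp3 (-2.45 ± 0.14). The highest adjusted p among the called genes of this paragraph was 0.00755, for Tnfsf8.

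Of 11 Ly49 genes, 9 were higher in CD8 Treg and 0 lower (10 and 0 adjusted over the list alone; list adjusted p = 5.23e-10, and adjusted p = 0.15 with an estimated correlation). Of 20 other NK cell receptor genes, 14 were higher and Klrg1 was lower (-3.53 ± 0.63), with 15 and 1 adjusted over the list alone (list adjusted p = 3.64e-09, and adjusted p = 0.451 with an estimated correlation). Klrc1 was higher by 5.86 ± 0.51. Of 18 cytotoxic genes, 12 were higher and Srgn was lower (-0.98 ± 0.16), with 13 and 1 adjusted over the list alone (list adjusted p = 3.92e-08, and adjusted p = 0.456 with an estimated correlation). Nkg7 (5.17 ± 0.23) and Prf1 (3.13 ± 0.26) were higher, and Gzmb did not pass (0.83 ± 0.45, adjusted p = 0.255). Of 15 CD8 memory genes, 12 were higher and Ly6a was lower (-2.40 ± 0.27), with 12 and 2 adjusted over the list alone (list adjusted p = 1.53e-08, and adjusted p = 0.15 with an estimated correlation). Eomes (5.85 ± 0.20), Tbx21 (4.75 ± 0.27) and the interleukin 7 receptor Il7r (1.55 ± 0.14) were higher. Of 19 terminal effector genes, 13 were higher, including Cxcr6 (4.74 ± 0.42), and S100a4 (-1.83 ± 0.24), Prdm1 (-1.77 ± 0.26) and Klrg1 were lower, with 14 and 3 adjusted over the list alone (list adjusted p = 1.34e-05, and adjusted p = 0.456 with an estimated correlation). Of 24 cell cycle genes, 7 were higher and 0 lower (10 and 0 adjusted over the list alone; list adjusted p = 0.000272, and adjusted p = 0.577 with an estimated correlation), including Top2a (1.47 ± 0.23). The highest adjusted p among the called genes of this paragraph was 0.00458, for Klrg1.

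Other cell types' genes were higher in CD8 Treg than in CD4 Treg. The NK cell list shares Gzma with the cytotoxic list and Eomes with the CD8 memory list, so the cells that made such transcripts are not settled. Of 16 B cell genes, 15 were higher and 0 lower (15 and 1 adjusted over the list alone; list adjusted p = 3.14e-12, and adjusted p = 0.15 with an estimated correlation), with Cd74 at 2.97 ± 0.12 (adjusted p = 1.84e-06). Of 14 monocyte, macrophage and neutrophil genes, 10 were higher and Ctss was lower (-0.88 ± 0.14, adjusted p = 0.00218), with 11 and 1 adjusted over the list alone (list adjusted p = 1.05e-06, and adjusted p = 0.357 with an estimated correlation). Of 12 NK cell genes, 11 were higher and Khdc1a was lower, the same adjusted over the list alone (list adjusted p = 7.70e-08, and adjusted p = 0.372 with an estimated correlation). The dendritic cell list (3 higher and 2 lower of 13, and 5 and 2 adjusted over the list alone; list adjusted p = 0.175), the gamma-delta T cell list (3 higher and 2 lower of 9, the same over the list alone; 0.862), the red cell and platelet list (1 higher of 10, Ppbp, and 0 adjusted over the list alone; 0.111) and the stroma list (1 lower of 4, Pecam1, the same over the list alone; 0.402) were not called.

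The naive list (6 higher and 3 lower of 15, and 7 and 4 adjusted over the list alone; list adjusted p = 0.142), interleukin receptors (3 and 5 of 18, the same over the list alone; 0.657), CD49 integrins and partner chains (2 and 3 of 8, the same over the list alone; 0.402) and chemokine receptors (7 and 6 of 17, and 8 and 6 adjusted over the list alone; 0.477) were not called and went both ways. T cell receptor complex genes (2 and 4 of 15, the same over the list alone; 0.318), glycolysis genes (1 and 2 of 15, and 3 and 3 adjusted over the list alone; 0.697), oxidative phosphorylation genes (0 of 22, the same over the list alone; 0.657) and the check genes (5 and 4 of 11, the same over the list alone; 0.695) were not called either. Among them, Itga2, which encodes CD49b, was higher in CD8 Treg (1.80 ± 0.48, adjusted p = 0.0313). It was called in 10 of 19 alternatives, with values of 1.43 to 2.45. Itga6 was lower in CD8 Treg (-1.91 ± 0.16, adjusted p = 7.69e-05).

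The test called 16 of 28 lists, 9 higher and 7 lower, and 0 with an estimated correlation, again on 2 residual degrees of freedom. By fry 17 were called. These left out the cytotoxic, terminal effector, interferon response and cell cycle lists and added 5 others. As above, fits without 1 library keep 1 residual degree of freedom. Most called genes that the naming rule covers lost their call without either CD49lo replicate. With a single CD8 Treg library, the gene count fell to 967 without CD4 Treg replicate 1, 833 without CD4 Treg replicate 2, 277 without CD49lo replicate 1 and 339 without CD49lo replicate 2. The 20 genes with the most extreme fold changes kept their call in 20, 20, 18 and 18 cases in that order.

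Some genes were called in both comparisons with CD49lo: 60 genes were higher, 274 were lower, and 103 were called in opposite directions. Il2rb, Bcl2 (0.73 ± 0.11 in CD4 Treg, 1.69 ± 0.13 in CD8 Treg) and Il4ra were among the shared higher genes. Gzmb (-5.31 ± 0.36 and -4.47 ± 0.45), Cx3cr1 (-6.27 ± 0.37 and -4.09 ± 0.46) and Top2a (-3.54 ± 0.19 and -2.07 ± 0.23) were among the shared lower genes. Those in opposite directions included Ctla4 (3.55 ± 0.22 and -2.62 ± 0.27), Nrp1 (3.00 ± 0.15 and -2.08 ± 0.18) and Klra3 (-2.16 ± 0.44 and 3.40 ± 0.54). These genes were chosen after their values were seen. Independent lists of these sizes would share 21.6 higher and 61.2 lower genes and hold 74.4 in opposite directions. In 100 simulations of unchanged groups against shared CD49lo libraries the means were 0.08, 0.11 and 0.03; these hold no changed genes, so any overlap of real changes exceeds them and they do not test for sharing. The fold changes of the 2 comparisons had a correlation of 0.364 across genes (simulated mean 0.409) and a covariance of 0.290 (simulated mean 0.0548, difference 0.235). The CD49lo libraries are too few to split between the comparisons, so the overlap may come from the shared controls, and a shared difference is not shown. The 334 genes shared in direction fell to 108 without CD4 Treg replicate 1, 76 without CD4 Treg replicate 2, 13 without CD49lo replicate 1 and 76 without CD49lo replicate 2.

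**Figure D4:**
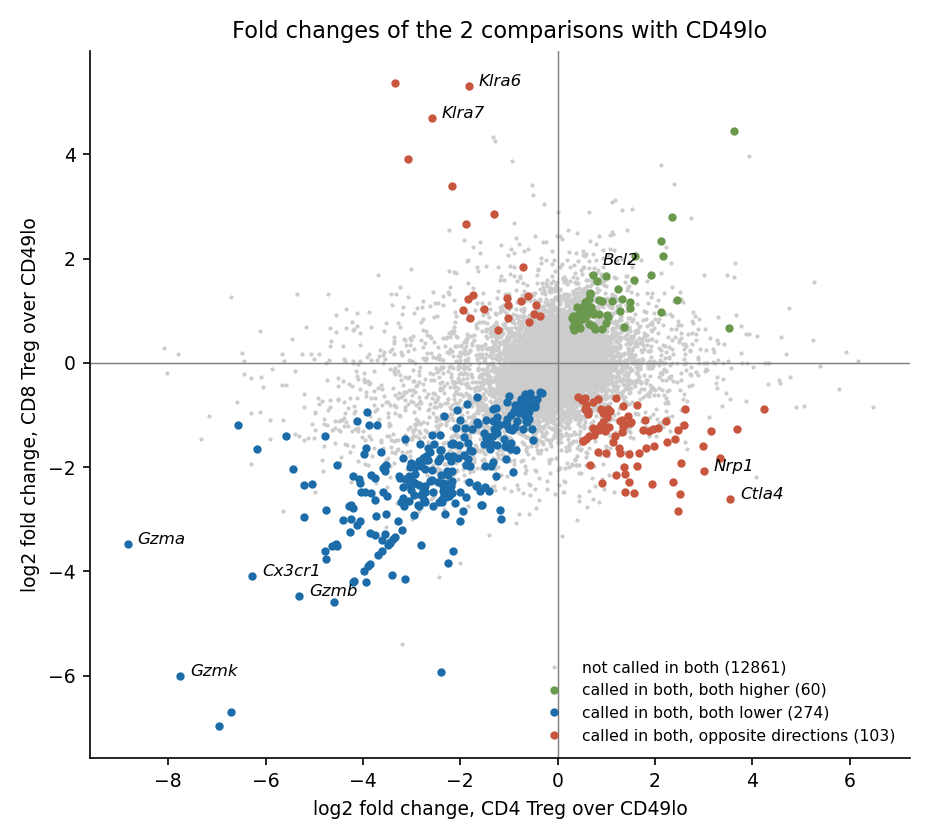
Log2 fold changes over CD49lo of CD4 Treg (horizontal axis) and CD8 Treg (vertical axis), with 1 point per gene tested; coloured points are genes called in both comparisons. The 274 shared lower genes fill the lower left and the 60 shared higher genes the upper right; fitted values of genes near or below 0.5 RPKM in a group depend on the pseudocount.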

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

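Of 9075 results for named genes over the alternatives, 7817 were as reported, called or not called, 1138 lost a call and 120 gained one. Among genes called in the reported fit, 0 results changed sign. A gene not called there was counted as reported when its sign changed, even where it became called. Cd3e in CD8 Treg against CD49lo, for example, ranged from -0.064 to 0.194. Removing the filter (21346 genes tested) left 704 called genes in CD4 Treg against CD49lo, 580 in CD8 Treg against CD49lo (494 higher and 86 lower), 1277 in CD8 Treg against CD4 Treg and 58 shared. A tested change above 1.5-fold left 1247, 150, 859 and 91. The RPKM prior gave 2491, 365, 1743 and 194, and with the RPKM filter 2019, 295, 1538 and 118; these were chosen after seeing the data. The 2 groups alone gave 1071 in CD8 Treg against CD4 Treg, with 1 residual degree of freedom. Leaving out 1 library gave 451 to 1457, 14 to 199 and 277 to 967 called genes and 13 to 108 shared. With an estimated correlation 0, 0 and 0 lists were called, and fry called 4 in CD8 Treg against CD49lo. The former setting takes p from 2 residual degrees of freedom, so it is not a check on correlation alone. Without a scaling factor the median log2 fold change shifted by -0.126 in CD8 Treg against CD49lo (170 genes higher and 656 lower) and by -0.101 in CD8 Treg against CD4 Treg. In CD8 Treg against CD49lo the integrin list lost its call without a scaling factor, with a pseudocount of 1 and with the RPKM prior and filter, and the cytotoxic and integrin lists without a filter. In the same comparison, without CD49lo replicate 1 the adjusted p of the CD8 memory, integrin and follicular lists was 0.097, 0.196 and 0.11, and without CD49lo replicate 2 that of the cytotoxic list 0.25; under these settings the other comparisons lost 0 lists. A replicate block gave 3577 called genes (1574 higher and 2003 lower) and 19 lists in CD4 Treg against CD49lo; deviations of libraries with the same number had a correlation of -0.0202 over 2 pairs, so the numbers are not shown to pair samples. Median-of-ratios scaling gave 2979, 716 and 2258 called genes, the stricter filter 3070, 773 and 2332, and robust moderation 3140, 871 and 2401. Among settings chosen after seeing the data, removal of X and Y genes gave 2908, 700 and 2202. The planned DESeq2 Wald test was not run and the older edgeR style of fit was not used, because count models were kept for values deposited as counts; of the count-based alternatives only limma-voom was run on the recovered reads.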

Other observations

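Of the tests below, those on sex genes, on the B cell mixture, on the total of other transcripts and on histone genes were chosen after the result had been seen; those on X and Y calls, on Rpl29 with its copies and on pseudogenes were written down before their values were computed.

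Histone genes were lower in CD8 Treg than in CD49lo, a family chosen after its values were seen. Of 64 replication-dependent histone genes tested, 53 were lower and 0 higher, with Hist1h3b at -3.48 ± 0.25 (adjusted p = 0.000275). In CD4 Treg against CD49lo, 57 were lower and 1 higher, and 10 and 15 were lower without CD49lo replicates 1 and 2. The lower of the percentages of histone and of cell cycle genes with fold changes below 0 was 96.9%; this restates values already seen, so a higher share of cycling cells in the CD49lo sort stays untested. These genes are near-identical copies, and without either CD49lo replicate 0 were called in CD8 Treg against CD49lo, with median log2 fold changes of -2.23 and -2.58. Of 81 ribosomal protein genes, also chosen after their values were seen, 66 were higher and 0 lower in CD8 Treg than in CD49lo, and 66 higher and 1 lower than in CD4 Treg. Without a scaling factor 60 and 53 were higher. Without either CD49lo replicate 0 were called higher, with median log2 fold changes over CD49lo of 0.74 and 0.75.

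Xist and Y-linked genes split the libraries by sorted population. All 5 genes tested (Xist, Ddx3y, Eif2s3y, Kdm5d and Uty) separated the CD4 Treg libraries from the other 3 in every library, which would suggest female CD4 Treg and male CD8 Treg and CD49lo donors. Genes on the X and Y chromosomes made up 2.40% of the called genes in CD4 Treg against CD49lo, against 3.26% of genes tested. With 427 X and 7 Y genes tested and 2964 genes called, they could not have been most of the calls. The prediction that they would be was bound to fail, so it does not measure how far sex shapes the calls. Effects of sex on other genes could not be separated from those of the population.

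B cell transcripts were higher in the CD8 Treg and CD49lo libraries than in CD4 Treg; Igkc was at 49.9 and 27.3 RPKM in CD4 Treg, 848 in CD8 Treg, and 1514 and 1322 in CD49lo. The 13 B cell genes with enough reads were all lower in CD8 Treg than in CD49lo, with a median log2 fold change of -0.94 and an SD of 0.273. The limit of 50 reads per library left out Pax5 (-1.59), Ly6d (-1.47) and Blk (-1.18) for their low reads in CD8 Treg, which narrows the SD, so it does not show that B cells or their RNA entered as 1 mixture. In CD49lo against CD4 Treg the median of the list lay 4.44 log2 units above that of all genes. A rise of every transcript alike would leave no such gap, so it cannot by itself set this list above the other genes. The list was examined because it was higher, so the gap was fixed in advance. It restates the excess, says nothing on its source and does not exclude a lower total of other transcripts in the CD8 Treg and CD49lo sorts. Ighm did not differ in the same way (log2 fold change of CD4 Treg over CD49lo 0.23 ± 0.19, adjusted p = 0.43), and a cell sort would be set up to remove B cells, so the source stays open.

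Rpl29 was 9.67-fold higher in CD4 Treg than in the mean of the other 3 libraries. With its near-identical copies (41 genes at 90% identity over at least 400 bases) the sum was 3.46-fold higher. Reads assigned to a copy instead could thus explain part of the difference but not all of it. Reads lost because they matched several copies would appear under no gene, so the sum cannot exclude them. Rpl29 alone held 1300 RPM (reads scaled to library depth) in CD4 Treg and 134 in the others, and the copies held 136 and 281. The copies thus offset only a small part of the difference in Rpl29 reads. The fold fell further because reads of the copies present in all libraries were added to both sides. Uimc1, a gene that spans the copy Gm6344, was counted among them. It held 79.3 and 103 RPM in CD4 Treg, 92.3 in CD8 Treg, and 98.2 and 92.9 in CD49lo, a large part of these totals. The opposite value of the copy Gm8210 had been seen before the sum was made. The share of reads in all pseudogenes differed by 1.09-fold between the means of CD4 Treg and of the other libraries. It was 0.616% and 0.641% in CD4 Treg, 0.786% in CD8 Treg, and 0.614% and 0.664% in CD49lo. This argues against a general gain or loss of pseudogene reads in CD4 Treg relative to CD49lo. The total cannot show reads moved between single pseudogenes. A strain variant in Rpl29 was not tested.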
